A study of Acomys cahirinus and Mus musculus with 24 samples.

How the data were processed

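The starting point was 3 deposited count tables with 46 count columns in all. The values in the table of each species are the authors' expected counts, estimated per gene and not all whole, and the values in the table shared by both species are the authors' counts, all whole. None of them is normalised. The submitters' notes name FastQC 0.11.4, Trimmomatic 0.32, RSEM 1.2.28, Bowtie2 with no version, and the mouse build mm9, without saying which step used which. The mouse table has 24090 features and the Acomys table has 144683, of which 16514 carry a gene symbol, 128120 carry only an assembly identifier and 49 are spike-in RNAs. The shared table has 14548 features, one per symbol, and no total under 110 counts; how it was made is not stated. An annotation table of the Acomys assembly, with no measurement, and raw reads were not used.

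Spike-in rows (0.68 to 1.96% of counts) were removed before library sizes were computed, and expected counts were rounded. The 2 species tables and the shared table were fitted separately, each with all its groups in 1 fit. Features with low counts were removed with filterByExpr by group, library sizes were scaled by TMM, and each contrast was tested with the quasi-likelihood F-test of edgeR (robust, two-sided) with no blocking term. Adjusted p is the Benjamini-Hochberg value over all features tested in a contrast, with 0.05 as the threshold. The common biological coefficient of variation was 0.218 in Mus, 0.213 in Acomys and 0.186 in the shared table. The SE of a log2 fold change was taken from the F statistic. There were 11 contrasts: 3 within each species, 3 between the species at one day, and 2 differences of changes, wound against skin in Acomys minus wound against skin in Mus. A gene with no count in any library of a group is given as at least a fold, with 3 counts over that group as the floor. Genes with 1 to 3 counts in a group are given as levels, with no fold.

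Each of 24 gene lists was tested with fry in limma, which asks whether the genes of a list move on balance one way and compares the list with no other genes. The p-values were adjusted over the lists of a contrast. The lists, fixed before the data were examined, were adult skeletal muscle, embryonic muscle and myogenesis, fibrillar collagen and scar matrix, myofibroblast and smooth muscle, matrix metalloproteinases and inhibitors, neutrophil, monocyte and macrophage, T and NK cell, B and plasma cell, cytokine and chemokine, interferon response, cell cycle, Wnt pathway, TGF-beta and BMP, hair follicle, epidermal differentiation, wound-edge keratinocyte, sebaceous and lipid synthesis, adipocyte, endothelial, Schwann cell and nerve, melanocyte, immediate early and handling, and red blood cell. The genes Des, Dgat2, Egr2, Il24, Lgr5, Mmp8, Ncam1, Pparg and Sox10 are each in 2 lists. Camera with an estimated correlation, or with a preset correlation of 0.01, was the alternative. Genes named in the text are 18 genes chosen beforehand, the 4 that rose most and the 4 that fell most in a contrast, and up to 3 members of each list in each direction; results for 2 of them are withheld and not reported here.

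Also fixed before the data were examined were the contrasts, the tests and these alternatives: RLE size factors, no filter on low counts, the DESeq2 Wald test, only the groups compared in the fit, replicate number as a block, a minimum of 2-fold, each library left out in turn, and Acomys counts summed by symbol with symbol-less features left out. Chosen after the data were seen were 2 more: leaving out the small structural RNAs, and leaving out 3 mouse wound libraries poor in muscle transcripts. Leaving out single libraries was added for the lists at that stage too.

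Whether equal replicate numbers mark one animal is not stated. The residual expression of libraries with the same number was correlated by 0.12 to 0.163 in the 3 pairs of Mus day 0 and day 7 and by 0.12 to 0.209 in the 3 pairs of Mus day 0 and day 14, above the 0.1 set as a limit, so blocked values are given where they change a call of these 2 contrasts. No pair of libraries was identical. The largest single features were Col3a1 (4.78% of counts) and the equal Rn7s1 and Rn7s2 (4.45% each) in Mus, Lars2 (8.34%) and an assembly feature without a symbol (6.66%) in Acomys, and Rn7s1 (5.21%) in the shared table.

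The fits were tested on data simulated with 200 changed genes per contrast and the real dispersions. Of 100 genes changed 2-fold 45 to 80% were recovered, of 100 changed 4-fold 82 to 99%, and 0 in the wrong direction. False calls were 2.82 to 7.26% of all calls. Of lists shifted 1.5-fold, fry and camera with an estimated correlation called 11 of 11 each, and 3 and 0 of 253 unchanged lists. Lists of correlated genes were not tested. Gene positions are from GENCODE vM21, a later build than the submitters'. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.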

Results

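RNA was sequenced from dorsal skin of Mus musculus (outbred CD-1 mice) and of Acomys cahirinus, the African spiny mouse, a rodent that heals skin wounds with little scarring. Each sample was unwounded skin (day 0) or a full-thickness excisional wound, 8 mm across when made, taken 7 or 14 days later. There were 4 libraries per species and day, except 3 for Mus day 0 (replicates 1, 2 and 4, because the submitters removed replicate 3 for poor quality). One further Acomys library, a pool normalised with duplex-specific nuclease, has no count column and was not analysed here. Total counts per library in the Mus table were 11023528 to 12939254 at day 0, 10148624 to 13052878 at day 7 and 9339214 to 13188137 at day 14. In the Acomys table they were 13090599 to 18037444 at day 0, 14521391 to 17674760 at day 7 and 15641918 to 18470245 at day 14. In the table of genes shared by both species, they were 5980683 to 9853153. These tables hold 15423 (Mus), 36053 (Acomys, of which 15283 have a gene symbol) and 14514 (shared) features that passed the filter on low counts.

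Genes carry the deposited symbols, older ones included (Emr1, now Adgre1). Gene values without a unit are log2 fold changes. List medians per library are of log2 levels, not on the scale of fitted fold changes. Values after ± are the SE for log2 fold changes. For levels in CPM, which are counts scaled by library size, they are the SD over a group's libraries. A gene is said to have risen or fallen only if its adjusted p was under 0.05 in the edgeR quasi-likelihood test over all genes. The adjusted p of a list is from fry, corrected over the 24 lists of a comparison, and its value with an estimated correlation between genes is from camera, which also compares the list with other genes. Groups of transcripts named as higher or lower are lists called by fry, most of them not called by camera. Member counts of a list are of those measured and passing over all genes, and the count adjusted over the list alone is given where it differs. The labels do not say whether the libraries of a group come from separate animals, so p-values measure the spread between libraries only. Intervals and fold floors cover counting error only. Reads can be shared among near-identical genes, so single values for Myh, S100, Hba, Stfa, Sprr and keratin family members are uncertain. On the mouse assembly GRCm38 (GENCODE vM21), the fast and developmental myosin genes lie side by side on chromosome 11, with Myh3 (embryonic) at 67078300-67102291 and Myh8 (perinatal) at 67277124-67308634. The protein-coding genes Tnc (4:63959785-64047015), Krt6a (15:101689910-101694307), Krt25 (11:99315516-99322951), Col3a1 (1:45311538-45349706), Ckm (7:19404776-19422841) and Acta1 (8:123891769-123894751) are also plotted or named often.

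The comparison of the Mus day 7 wound with Mus skin asks what a mouse wound expresses early in healing. Transcripts of neutrophils, macrophages, cytokines, dividing cells, blood vessels and wound-edge keratinocytes were higher than in skin. Transcripts of fat, sebaceous gland, Schwann cells and pigment cells were lower. Tnc, Postn and Loxl3 rose while Col1a1 and Col1a2 fell. Muscle differed widely between wound libraries.

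In Mus at day 7, 8881 of 15423 genes passed, 4515 higher and 4366 lower. In the neutrophil list 17 of 19 rose and 1 fell (adjusted p = 2.61e-05, and 0.172 with an estimated correlation). The calcium-binding S100a8 and S100a9 rose by 8.71 ± 0.817 and 8.56 ± 0.772, the granulocyte receptor Csf3r by 5.73 ± 0.467 and the lectin Clec4d by 8.76 ± 0.657. Against the list's name, Mpo, a granule enzyme made by immature neutrophils, fell by 5.15 ± 0.266. In the monocyte and macrophage list 21 of 25 rose and 1 fell (adjusted p = 1.26e-04, and 0.267 with an estimated correlation). Its members Itgam, Lyz2 and Emr1 rose by 2.84 ± 0.208, 2.47 ± 0.188 and 0.99 ± 0.229, while Gpnmb, a marker of lipid-laden macrophages, fell by 2.12 ± 0.146. In the cytokine and chemokine list 22 of 30 rose and 1 fell (adjusted p = 2.61e-05, and 0.172 with an estimated correlation). The chemokine Ccl3 had no count in day 0 skin and was at least 1990-fold higher. Cxcl2, which draws neutrophils, rose by 12.05 ± 1.91, Il1b by 8.73 ± 0.88, Il1a by 3.53 ± 0.206 and the alarmin Il33 by 3.12 ± 0.209, while the skin chemokine Cxcl14 fell by 1.52 ± 0.279.

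In the fibrillar collagen and scar matrix list of Mus at day 7, 25 of 30 rose and 3 fell (adjusted p = 3.89e-06, and 0.172 with an estimated correlation). Tenascin C (Tnc), a provisional-matrix protein, rose by 6.56 ± 0.428, adjusted p = 1.08e-06, from 34.7 ± 13.3 to 3286 ± 413 CPM. Periostin (Postn) rose by 1.93 ± 0.218, Col12a1 by 5.83 ± 0.266 and the lysyl oxidase Loxl3 by 3.83 ± 0.185, but Col1a2 fell by 1.12 ± 0.102 and the collagen-binding Sparc by 0.79 ± 0.0905. Col3a1 was at 0.12 ± 0.12, adjusted p = 0.432. Col1a1 fell by 0.88 ± 0.306 (adjusted p = 0.0302), a call lost without Mus day 0 replicate 1, 2 or 4 or Mus day 7 replicate 3 or 4, adjusted p = 0.0508 to 0.0855. The myofibroblast actin Acta2 rose by 1.38 ± 0.232 and the collagen receptor Itga11 by 2.06 ± 0.311, while smooth-muscle Myh11 fell by 2.001 ± 0.177. The list of matrix metalloproteinases and inhibitors was higher (14 of 24 rose and 5 fell, adjusted p = 1.73e-05, and 0.172 with an estimated correlation). In the cell cycle list 31 of 33 rose and 0 fell, 31 and 1 adjusted over the list alone (adjusted p = 7.69e-06, and 0.172 with an estimated correlation), including Mki67 (1.09 ± 0.152). In the Wnt pathway list 13 of 50 rose and 28 fell, and the test was downward (adjusted p = 6.99e-05, and 0.267 with an estimated correlation).

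In the wound-edge keratinocyte list of Mus at day 7, 21 of 25 rose and 1 fell (adjusted p = 3.18e-05, and 0.217 with an estimated correlation). Krt6a, a keratin of activated keratinocytes, rose by 4.95 ± 0.502, adjusted p = 1.88e-05, the gap-junction gene Gjb2 by 5.95 ± 0.465 and the urokinase receptor Plaur by 4.44 ± 0.248, while the hemidesmosome integrin Itgb4 fell by 0.68 ± 0.154. The hair follicle list was not called: 17 of 33 rose and 10 fell, with a median of 2.63 and a downward test (adjusted p = 0.397). Its medians in replicates 1 to 4 were -0.18, 2.416, 0.194 and 1.939. Padi3 and Krt71 of the inner root sheath rose by 3.35 ± 0.701 and 7.25 ± 1.93, while the bulge keratin Krt15, Lhx2 and Gata3 fell by 6.50 ± 0.367, 4.85 ± 0.465 and 3.42 ± 0.247. In the adipocyte list 0 of 21 rose and 20 fell (adjusted p = 1.72e-04, and 0.282 with an estimated correlation). Adipoq was at -3.51 ± 0.872 and Pparg at -1.98 ± 0.185. In the sebaceous and lipid synthesis list 2 of 20 rose and 17 fell (adjusted p = 1.23e-06, and 0.0933 with an estimated correlation), and Scd1 fell by 4.57 ± 0.197. The endothelial list was higher (16 of 22 rose and 1 fell, adjusted p = 2.61e-05, and 0.175 with an estimated correlation). Pecam1 was at 1.98 ± 0.143 and Tie1 at 1.96 ± 0.138, while lymphatic Prox1 fell by 2.04 ± 0.345. The lists of Schwann cell and nerve (2 of 16 rose and 11 fell, 2 and 12 adjusted over the list alone, adjusted p = 1.72e-04, and 0.311 with an estimated correlation) and melanocyte genes (0 of 9 rose and 5 fell, adjusted p = 9.25e-04, and 0.466 with an estimated correlation) were lower, with Erbb3 at -1.85 and the pigment enzyme Dct at -2.66. The immediate early and handling (adjusted p = 0.008, and 0.632 with an estimated correlation) and red blood cell lists (adjusted p = 0.00121, and 0.419 with an estimated correlation) were higher.

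Muscle transcripts in Mus at day 7 depended on the library: the median of the adult skeletal muscle list against day 0 was -2.71, -2.19, -6.76 and -2.82 in replicates 1 to 4. That list was not called (0 of 40 rose and 8 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.137), and with 3 muscle-poor libraries (Mus day 7 replicate 3, Mus day 14 replicates 2 and 3) left out its adjusted p was 0.012. The embryonic muscle and myogenesis list was not called either (adjusted p = 0.397), though Myh3 rose by 4.19 ± 0.924, from 0.465 ± 0.106 to 8.72 ± 5.57 CPM, and the embryonic light chain Myl4 by 2.59 ± 0.561. Ckm (-3.16, adjusted p = 0.164), Acta1 (-3.54, 0.108), Myod1 (-1.05, 0.208) and Myog (-0.03, 0.974) did not pass. Ckm and Acta1 did with only the groups compared (adjusted p = 0.0358 and 0.0272) and without the 3 muscle-poor libraries (adjusted p = 0.0031 and 6.34e-04). Pax7, the satellite-cell factor, is in neither the Mus nor the shared table. Myh8 was at 1.26 (adjusted p = 0.251); the call was made without Mus day 7 replicate 3, adjusted p = 0.00189, and with replicate number as a block (adjusted p = 0.0152). The T and NK cell and interferon response lists were not called (adjusted p = 0.298 and 0.239), but were with the block (adjusted p = 0.0285 and 0.0167).

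The comparison of the Mus day 14 wound with Mus skin asks what still differs later in healing. Scar matrix, macrophage, neutrophil and wound-edge keratinocyte transcripts remained above skin, and fat and sebaceous transcripts remained below it. Col3a1, which was not changed at day 7, was higher. The hair follicle list was not called. Embryonic muscle genes were lower than in skin, a call that most fits without 1 library lost.

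In Mus at day 14, 7077 genes passed, 3582 higher and 3495 lower. In the fibrillar collagen and scar matrix list 26 of 30 rose and 2 fell (adjusted p = 4.09e-06, and 0.0582 with an estimated correlation). Col3a1 was at 0.79 ± 0.122, adjusted p = 4.29e-04, Tnc at 5.36 ± 0.404, Postn at 2.72 ± 0.226, Col12a1 at 5.87 ± 0.266 and Col5a2 at 1.61 ± 0.0814. Col1a1 was at -0.24 ± 0.307, adjusted p = 0.558, and passed without Mus day 14 replicate 2, adjusted p = 0.0485, and without 3 muscle-poor libraries (-0.843, adjusted p = 0.00333). The fibroblast protease Fap rose by 2.22 ± 0.23 and Itga11 by 3.54 ± 0.33, while contractile Myh11 and Cnn1 fell by 1.80 ± 0.176 and 3.20 ± 0.293 and Acta2 was at 0.20 ± 0.224, adjusted p = 0.5. In the list of matrix metalloproteinases and inhibitors 17 of 24 rose and 2 fell (adjusted p = 1.16e-05, and 0.0582 with an estimated correlation). The neutrophil list (12 of 19 rose and 2 fell, adjusted p = 0.00572, and 0.584 with an estimated correlation) and the monocyte and macrophage list (21 of 25 rose and 1 fell, adjusted p = 7.72e-04, and 0.431 with an estimated correlation) were higher. S100a8 rose by 5.32 ± 0.724, Clec4d by 5.53 ± 0.639, Emr1 by 0.97 ± 0.229, the lipid receptor Trem2 by 4.21 ± 0.365 and the fractalkine receptor Cx3cr1 by 2.40 ± 0.224, while Mpo fell by 6.57 ± 0.303. The cytokine and chemokine list was higher (15 of 30 rose and 1 fell, 16 and 1 adjusted over the list alone, adjusted p = 0.00572, and 0.584 with an estimated correlation).

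In the wound-edge keratinocyte list of Mus at day 14, 18 of 25 rose and 2 fell (adjusted p = 0.00132, and 0.504 with an estimated correlation). Krt6a was at 3.89 ± 0.475, adjusted p = 1.07e-04, Krt16 at 5.64 ± 0.649 and Gjb2 at 4.88 ± 0.442. In the hair follicle list 20 of 33 rose and 6 fell, with a median of 4.57, but the test did not pass (adjusted p = 0.241). The inner-root-sheath keratin Krt73 had no count in skin and was at least 247-fold higher, and Krt25 was at 94.2 ± 25.0 CPM against 0.0295 ± 0.0512 CPM (adjusted p = 0.00334). Padi3 and Krt71 rose by 4.90 ± 0.682 and 8.77 ± 1.97, while Krt15 and the ectodysplasin receptor Edar fell by 4.60 ± 0.337 and 3.56 ± 0.354. In the adipocyte list 0 of 21 rose and 20 fell (adjusted p = 7.37e-05, and 0.367 with an estimated correlation). Adipoq was at -3.86 ± 0.891. In the sebaceous and lipid synthesis list 1 of 20 rose and 18 fell (adjusted p = 3.23e-07, and 0.0227 with an estimated correlation). The endothelial list (14 of 22 rose and 0 fell, 15 and 0 adjusted over the list alone, adjusted p = 3.14e-04, and 0.367 with an estimated correlation) and the cell cycle list (14 of 33 rose and 1 fell, 15 and 1 adjusted over the list alone, adjusted p = 0.00653, and 0.78 with an estimated correlation) were higher, and the latter was not called without the 3 muscle-poor libraries (adjusted p = 0.0658). Pecam1 rose by 1.41 ± 0.14. Mki67 rose by 0.42 ± 0.15, adjusted p = 0.0382, a call lost without Mus day 0 replicate 1 or 2 or Mus day 14 replicate 1, 2, 3 or 4, adjusted p = 0.0527 to 0.158. The Schwann cell and nerve list was lower (1 of 16 rose and 6 fell, adjusted p = 0.00468, and 0.683 with an estimated correlation).

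The adult skeletal muscle list of Mus at day 14 had medians of -1.35, -7.31, -7.16 and -3.25 against day 0 in replicates 1 to 4. It was not called (3 of 40 rose and 10 fell, 0 and 2 adjusted over the list alone, adjusted p = 0.0578; 1 of 7 fits without 1 library made the call, adjusted p 0.0186 to 0.131; adjusted p = 0.0314 without the 3 muscle-poor libraries). Ckm was at -2.90 ± 1.81, adjusted p = 0.217 and Acta1 at -3.62 ± 1.75, adjusted p = 0.118, with levels of 262 ± 378 CPM against 3225 ± 188 CPM for Acta1; without the 3 muscle-poor libraries both passed (adjusted p = 0.0366 and 0.00505). In the embryonic muscle and myogenesis list 2 of 20 rose and 11 fell (adjusted p = 0.0443, and 0.818 with an estimated correlation), and 6 of 7 fits without 1 library lost the call, adjusted p 0.0325 to 0.128. Myh3 was at 0.51 ± 1.09, adjusted p = 0.726. Myod1, the myoblast factor, was at 0.0242 ± 0.0485 CPM against 1.41 ± 0.604 CPM (adjusted p = 0.00278). Myog, its partner in differentiation, fell by 3.22 (adjusted p = 0.0229), a call lost without Mus day 0 replicate 4 or Mus day 14 replicate 2, 3 or 4, adjusted p = 0.0504 to 0.104. Myh8 fell by 3.10 ± 1.08 (adjusted p = 0.0387), a call lost without Mus day 0 replicate 1, 2 or 4 or Mus day 14 replicate 2, 3 or 4, adjusted p = 0.0666 to 0.0899. The red blood cell list was higher (2 of 7 rose and 0 fell, 0 and 0 adjusted over the list alone, adjusted p = 0.0443, and 0.818 with an estimated correlation), but 6 of 7 fits without 1 library lost the call, adjusted p 0.0397 to 0.147, and with replicate number as a block adjusted p was 0.067. The B and plasma cell and interferon response lists passed with the block (adjusted p = 0.0099 and 0.0142, against 0.171 and 0.175), and the latter without the 3 muscle-poor libraries (adjusted p = 0.0341).

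The comparison of Mus day 14 with Mus day 7 asks how the mouse wound matures. Neutrophil, cytokine, mitotic and wound-edge transcripts fell from the first wound age to the next. Col1a2, Col3a1 and several Wnt and hair follicle genes rose. Myh3 and Myh8 fell, but the embryonic muscle list was not called.

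Between these Mus wounds, 3685 genes passed, 1659 higher and 2026 lower at day 14. In the neutrophil list 0 of 19 rose and 17 fell, 0 and 18 adjusted over the list alone (adjusted p = 2.09e-04, and 0.0812 with an estimated correlation), and in the cytokine and chemokine list 1 of 30 rose and 22 fell, 1 and 24 adjusted over the list alone (adjusted p = 2.09e-04, and 0.0812 with an estimated correlation). S100a8 fell by 3.39 ± 0.539, Csf3r by 3.35 ± 0.358, Il1a by 2.64 ± 0.175, Tnf by 3.72 ± 0.426 and the neutrophil-derived lipocalin Lcn2 by 5.35 ± 0.84, while Gpnmb rose by 1.56 ± 0.138. In the cell cycle list 0 of 33 rose and 32 fell (adjusted p = 2.09e-04, and 0.108 with an estimated correlation): Mki67 fell by 0.66 ± 0.138. Col1a2 rose by 0.58 ± 0.0958, Col3a1 by 0.67 ± 0.111, Postn by 0.78 ± 0.19 (adjusted p = 0.123 without the 3 muscle-poor libraries) and the proteoglycan Lum by 0.66 ± 0.123, whereas Tnc fell by 1.204 ± 0.298, Acta2 by 1.19 ± 0.209 and the collagen prolyl hydroxylase P4ha1 by 0.68 ± 0.0997. The fibrillar collagen and scar matrix list was not called (adjusted p = 0.432), nor was Col1a1 (0.64 ± 0.286, adjusted p = 0.13). In the list of matrix metalloproteinases and inhibitors 7 of 24 rose and 3 fell, 9 and 4 adjusted over the list alone (adjusted p = 0.0405, and 0.442 with an estimated correlation), but 7 of 8 fits without 1 library lost the call, adjusted p 0.00227 to 0.132. The Wnt pathway list was higher (21 of 50 rose and 2 fell, adjusted p = 6.90e-04, and 0.108 with an estimated correlation). The hair follicle list was higher too (9 of 33 rose and 0 fell, adjusted p = 0.0166, and 0.442 with an estimated correlation), but not without the 3 muscle-poor libraries (adjusted p = 0.123).

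From Mus day 7 to day 14, 0 of 25 rose and 7 fell, 0 and 16 adjusted over the list alone, in the wound-edge keratinocyte list (adjusted p = 0.00518, and 0.396 with an estimated correlation). Krt6a was at -1.06 ± 0.378, adjusted p = 0.0675, and passed without Mus day 14 replicate 3, adjusted p = 0.0111, with DESeq2 or the block (adjusted p = 0.0167 and 0.015) and without the 3 muscle-poor libraries (adjusted p = 0.0275). In the endothelial list 3 of 22 rose and 13 fell (adjusted p = 0.0155, and 0.442 with an estimated correlation), a call lost without the 3 muscle-poor libraries (adjusted p = 0.0641). Pecam1 was at -0.57 ± 0.125. Myh3 fell by 3.68 ± 0.803, Myl4 by 2.11 ± 0.496 and Myh8 by 4.36 ± 1.03. Their list, embryonic muscle and myogenesis, was not called (1 of 20 rose and 7 fell, 1 and 9 adjusted over the list alone, adjusted p = 0.212), but was without Mus day 7 replicate 3 (adjusted p = 0.00054) or the 3 muscle-poor libraries (adjusted p = 0.00821). Myog fell by 3.18 ± 0.971 (adjusted p = 0.0371), a call lost without Mus day 7 replicate 1, 2 or 4 or Mus day 14 replicate 2, 3 or 4, adjusted p = 0.0692 to 0.0947. Myod1 was at 0.0242 ± 0.0485 CPM against 0.688 ± 0.466 CPM (adjusted p = 0.0253), and lost the call without Mus day 7 replicate 1 or 4 or Mus day 14 replicate 1, 2, 3 or 4, adjusted p = 0.0552 to 0.0665. The adult skeletal muscle list was not called (median 0.08, mean 0.23, test downward, adjusted p = 0.777). Ckm was at 0.26 ± 1.63, adjusted p = 0.932 and Acta1 at -0.08 ± 1.53, adjusted p = 0.978. Emr1 (-0.02 ± 0.207, adjusted p = 0.965) and Adipoq (-0.35 ± 0.875, adjusted p = 0.813) did not pass.

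The comparison of the Acomys day 7 wound with Acomys skin asks what a spiny mouse wound expresses at the same age. Adult muscle genes were far below skin in all 4 wound libraries while embryonic muscle genes were already above it. Scar matrix, neutrophil, macrophage and cell cycle transcripts were higher. Hair follicle, fat, sebaceous, pigment and nerve transcripts were lower.

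In Acomys at day 7, 15541 of 36053 features passed (8233 of the 15283 with a symbol), 7654 higher and 7887 lower. In the adult skeletal muscle list 0 of 39 rose and 37 fell (adjusted p = 1.49e-04, and 0.252 with an estimated correlation), and its median per library lay between -3.47 and -2.02. Creatine kinase Ckm fell by 4.54 ± 0.507 (adjusted p = 2.76e-05), Acta1 by 1.08 ± 0.226, the slow troponin Tnnt1 by 1.64 ± 0.223 and Dmd by 1.95 ± 0.206. In the embryonic muscle and myogenesis list 12 of 25 rose and 4 fell (adjusted p = 0.00698, and 0.517 with an estimated correlation). Myh3 rose by 4.87 ± 0.533, adjusted p = 2.44e-05, from 2.53 ± 2.05 to 73.0 ± 22.3 CPM, and Myog by 1.61 ± 0.352, cardiac-type actin Actc1 by 4.03 ± 0.279 and Myl4 by 4.98 ± 0.419. Pax7 was at 0.65 ± 0.475, adjusted p = 0.289, and Myod1 at -0.71 ± 0.339, adjusted p = 0.103, passing without Acomys day 7 replicate 1, adjusted p = 0.0406. Perinatal Myh8 was at 0.0143 ± 0.0287 CPM against 0.68 ± 0.351 CPM in skin (adjusted p = 1.07e-04). The fibrillar collagen and scar matrix list was higher (27 of 30 rose and 0 fell, 28 and 0 adjusted over the list alone, adjusted p = 5.48e-07, and 0.0226 with an estimated correlation). Tnc rose by 7.47 ± 0.257, adjusted p = 1.87e-12, from 30.5 ± 3.44 to 5412 ± 1070 CPM, Postn by 1.88 ± 0.246, the lysyl oxidase Lox by 3.78 ± 0.17 and Col3a1 by 0.80 ± 0.24, while Col1a1 was at 0.39 ± 0.292, adjusted p = 0.31 and passed without Acomys day 0 replicate 1, adjusted p = 0.00958. With counts summed by symbol Col3a1 had adjusted p = 0.0509. Acta2 rose by 0.71 ± 0.205 and Itga11 by 3.01 ± 0.2, while the myofibroblast and smooth muscle list as a whole was lower (5 of 16 rose and 9 fell, adjusted p = 0.00257, and 0.47 with an estimated correlation).

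In the neutrophil list of Acomys at day 7, 12 of 15 rose and 1 fell (adjusted p = 1.43e-06, and 0.0228 with an estimated correlation). S100a8 was at 7.56 ± 0.452, adjusted p = 4.80e-08, the formyl-peptide receptor Fpr1 at 8.22 ± 0.516 and Cxcr2 at 3.60 ± 0.271. The monocyte and macrophage list was higher (17 of 22 rose and 3 fell, adjusted p = 1.31e-05, and 0.0895 with an estimated correlation): the scavenger receptor Cd163, C1qa and Emr1 rose by 4.49 ± 0.356, 3.50 ± 0.294 and 2.14 ± 0.467, but Arg1 fell by 2.52 ± 0.292. The acute-phase gene Saa3 had no count in skin and was at least 403-fold higher. In the cytokine and chemokine list 20 of 30 rose and 6 fell, 21 and 6 adjusted over the list alone (adjusted p = 3.91e-04, and 0.254 with an estimated correlation). The list of matrix metalloproteinases and inhibitors (18 of 24 rose and 2 fell, adjusted p = 1.21e-06, and 0.0348 with an estimated correlation) and the cell cycle list (28 of 33 rose and 1 fell, 29 and 1 adjusted over the list alone, adjusted p = 6.29e-05, and 0.175 with an estimated correlation) were higher, with collagenase Mmp13 at 8.59 ± 0.383 and Mki67 at 1.44 ± 0.156. In the hair follicle list 0 of 32 rose and 21 fell, 0 and 23 adjusted over the list alone (adjusted p = 6.23e-04, and 0.288 with an estimated correlation). Its median per library was 1.371 in Acomys day 0 replicate 2, -0.388 to -0.376 in the other 3 skin libraries and -1.768 to -1.621 in the wounds, so the size of the fall leans on 1 skin library. The wound-edge keratinocyte list was higher (18 of 25 rose and 1 fell, 18 and 2 adjusted over the list alone, adjusted p = 4.84e-08, and 0.00442 with an estimated correlation), and Krt6a rose by 4.66 ± 0.202. The epidermal differentiation list was lower (3 of 25 rose and 9 fell, 3 and 10 adjusted over the list alone, adjusted p = 0.0314, and 0.632 with an estimated correlation), but 5 of 8 fits without 1 library lost the call, adjusted p 0.00783 to 0.14.

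The adipocyte (0 of 21 rose and 20 fell, adjusted p = 1.84e-07, and 0.00942 with an estimated correlation) and sebaceous and lipid synthesis lists (2 of 20 rose and 18 fell, adjusted p = 4.53e-07, and 0.00942 with an estimated correlation) fell in Acomys at day 7, with Adipoq at -6.77 ± 0.282 and Elovl6 at -3.58 ± 0.2. The endothelial list rose (13 of 22 rose and 1 fell, 14 and 1 adjusted over the list alone, adjusted p = 2.67e-04, and 0.272 with an estimated correlation). Pecam1 was at 0.90 ± 0.139 and Lyve1 at 3.07 ± 0.204. The Schwann cell and nerve (3 of 19 rose and 14 fell, 3 and 15 adjusted over the list alone, adjusted p = 2.93e-05, and 0.16 with an estimated correlation) and melanocyte lists (1 of 10 rose and 4 fell, adjusted p = 0.00335, and 0.47 with an estimated correlation) fell, with Sox10 at -2.90 ± 0.296. The Wnt pathway list fell (adjusted p = 0.00712, and 0.591 with an estimated correlation), but 2 of 8 fits without 1 library lost the call, adjusted p 0.00725 to 0.125. The interferon response list rose (adjusted p = 0.0227, and 0.591 with an estimated correlation), but 4 of 8 fits without 1 library lost the call, adjusted p 0.00308 to 0.0646. The immediate early and handling and red blood cell lists were not called (adjusted p = 0.707 and 0.386).

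The comparison of the Acomys day 14 wound with Acomys skin addresses the muscle regeneration named in the title of the series. Embryonic muscle genes were above skin in all 4 libraries, the myogenic factors rose, and adult muscle genes were back near the level of skin. Scar matrix genes were still higher, together with Wnt and TGF-beta genes. The wound-edge keratinocyte list was not called, and Krt6a was below skin.

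In Acomys at day 14, 7998 features passed (4756 with a symbol), 4222 higher and 3776 lower. In the embryonic muscle and myogenesis list 21 of 25 rose and 0 fell, 22 and 0 adjusted over the list alone (adjusted p = 2.79e-05, and 0.0207 with an estimated correlation). Myh3 rose by 5.77 ± 0.549, adjusted p = 3.04e-05, to 137 ± 34.4 CPM. The myogenic factors Myod1 and Myog rose by 1.23 ± 0.31, adjusted p = 0.00681 and 2.82 ± 0.347, adjusted p = 1.52e-05, Pax7 by 1.58 ± 0.445, Actc1 by 5.43 ± 0.292, embryonic troponin Tnnt2 by 3.50 ± 0.293 and Myl4 by 6.41 ± 0.391. The adult skeletal muscle list was not called (6 of 39 rose and 0 fell, median 0.30, adjusted p = 0.278), with per-library medians of -0.387 to 0.933. Ckm (0.21 ± 0.435, adjusted p = 0.803) and Myh8 (0.42 ± 0.44, adjusted p = 0.567) did not pass, and Acta1 (0.37 ± 0.224, adjusted p = 0.268) passed without Acomys day 0 replicate 1, adjusted p = 0.0473. In the fibrillar collagen and scar matrix list 29 of 30 rose and 0 fell (adjusted p = 3.80e-06, and 0.0081 with an estimated correlation). Tnc was at 5.13 ± 0.231, Lox at 3.21 ± 0.166, Postn at 2.39 ± 0.25 and Col3a1 at 1.504 ± 0.244, adjusted p = 1.96e-04. Col1a1 rose by 0.97 ± 0.294, adjusted p = 0.0276, a call lost without Acomys day 0 replicate 2, 3 or 4 or Acomys day 14 replicate 1 or 4, adjusted p = 0.0504 to 0.0822. Among the largest increases were the angiotensin receptor Agtr2 (8.05 ± 0.713) and the adipokine C1qtnf3 (6.77 ± 0.296).

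In the Wnt pathway list of Acomys at day 14, 23 of 51 rose and 11 fell, 25 and 11 adjusted over the list alone (adjusted p = 0.00342, and 0.31 with an estimated correlation). The TGF-beta and BMP list was higher (14 of 36 rose and 4 fell, 19 and 5 adjusted over the list alone, adjusted p = 0.00612, and 0.388 with an estimated correlation). The metalloproteinase (adjusted p = 2.79e-05, and 0.0228 with an estimated correlation), macrophage (adjusted p = 3.44e-04, and 0.0838 with an estimated correlation) and cell cycle lists (23 of 33 rose and 1 fell, 27 and 2 adjusted over the list alone, adjusted p = 0.00445, and 0.294 with an estimated correlation) were higher. Mki67 rose by 1.01 ± 0.155. Emr1 rose by 1.55 ± 0.464, adjusted p = 0.0346, a call lost without Acomys day 0 replicate 2 or 3 or Acomys day 14 replicate 2 or 3, adjusted p = 0.0752 to 0.108. The neutrophil list was not called (adjusted p = 0.0792), though 1 of 8 fits without 1 library made the call, adjusted p 0.0288 to 0.345. S100a8 rose by 1.46 ± 0.372, adjusted p = 0.0132, a call lost without Acomys day 0 replicate 3, adjusted p = 0.0592. Acta2 fell by 0.70 ± 0.205 (adjusted p = 0.019), a call lost without Acomys day 0 replicate 2 or Acomys day 14 replicate 1, 2 or 4, adjusted p = 0.0534 to 0.0978, and Myh11 fell by 1.54 ± 0.222. The wound-edge keratinocyte list was not called (3 of 25 rose and 9 fell, 5 and 10 adjusted over the list alone, adjusted p = 0.0694), though 1 of 8 fits without 1 library made the call, adjusted p 0.00221 to 0.211. Krt6a fell by 1.23 ± 0.178 (adjusted p = 5.33e-05), from 99.1 ± 29.2 to 42.2 ± 4.66 CPM. The epidermal differentiation list was lower (1 of 25 rose and 12 fell, 2 and 15 adjusted over the list alone, adjusted p = 0.0196, and 0.388 with an estimated correlation), but 3 of 8 fits without 1 library lost the call, adjusted p 0.00446 to 0.0862. In the hair follicle list 7 of 32 rose and 4 fell, 9 and 4 adjusted over the list alone (adjusted p = 0.153, but 0.02 with the block), and 1 of 8 fits without 1 library made the call, adjusted p 0.0284 to 0.345. Shh was at 2.55 ± 0.326, Msx2 at 1.78 ± 0.359 and Krt15 at -2.40 ± 0.28. The adipocyte (adjusted p = 3.29e-05, and 0.0202 with an estimated correlation) and sebaceous lists (adjusted p = 3.29e-05, and 0.0202 with an estimated correlation) were lower, with Adipoq at -2.30 ± 0.216. The endothelial (adjusted p = 0.00254, and 0.294 with an estimated correlation) and melanocyte lists (adjusted p = 0.00562, and 0.294 with an estimated correlation) were higher, with Dct at 3.67 ± 0.447. Pecam1 was at 0.35 ± 0.138, adjusted p = 0.0838, and passed with counts summed by symbol (adjusted p = 0.0278).

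**Figure D1:**
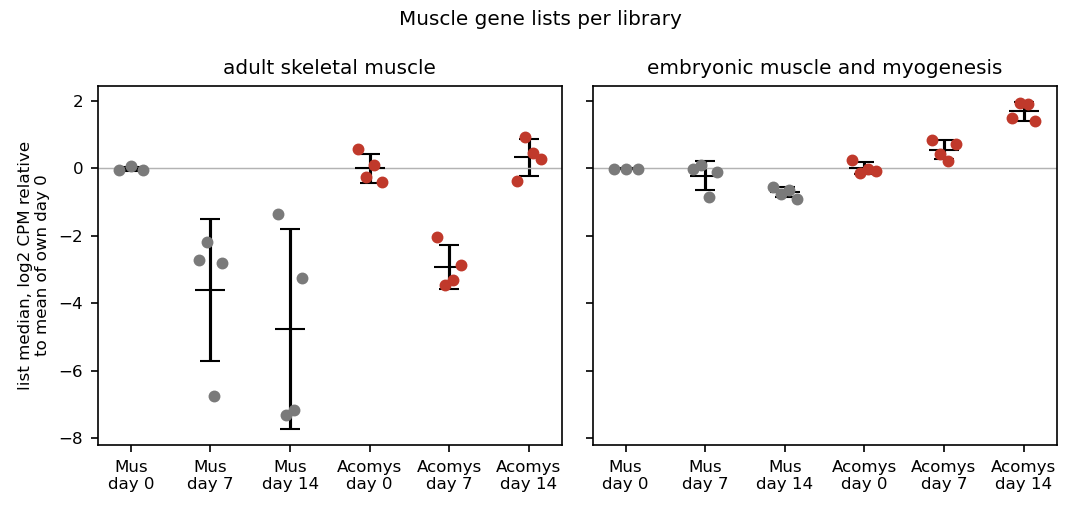
Median log2 level of the adult skeletal muscle (left) and embryonic muscle and myogenesis lists (right), relative to mean day 0 skin of the species. Points are libraries, and bars the mean and SD of each group. In the adult list the 4 Acomys day 14 libraries lie between -0.387 and 0.933 and the 4 Mus day 14 libraries between -7.31 and -1.35.

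The comparison of Acomys day 14 with Acomys day 7 asks which programmes return as the spiny mouse wound matures. Adult muscle, hair follicle, fat, sebaceous, nerve and pigment transcripts rose. Neutrophil, cytokine, mitotic and wound-edge keratinocyte transcripts fell.

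Between these Acomys wounds, 9445 features passed (5324 with a symbol), 5164 higher and 4281 lower at day 14. In the adult skeletal muscle list 39 of 39 rose and 0 fell (adjusted p = 9.10e-05, and 0.0709 with an estimated correlation). Ckm was at 4.74 ± 0.511, adjusted p = 5.49e-05, Acta1 at 1.46 ± 0.228 and Tnnt1 at 2.46 ± 0.227. In the embryonic list 21 of 25 rose and 0 fell, 24 and 0 adjusted over the list alone (adjusted p = 9.10e-05, and 0.0775 with an estimated correlation). Myod1 was at 1.93 ± 0.323, Myog at 1.204 ± 0.309 and the satellite-cell receptor Megf10 at 1.29 ± 0.19, while Myh3 (0.91 ± 0.428, adjusted p = 0.154) and Pax7 (0.93 ± 0.414, adjusted p = 0.111) did not pass, though Myh3 did with only the groups compared (adjusted p = 0.0147). Myh8 was at 0.957 ± 0.524 CPM against 0.0143 ± 0.0287 at day 7 (adjusted p = 6.43e-05). The myofibroblast and smooth muscle list rose (adjusted p = 0.00461, and 0.329 with an estimated correlation). Myh11 was at 1.95, although Acta2 fell by 1.41 ± 0.208 and Tagln by 1.34 ± 0.268. In the hair follicle list 29 of 32 rose and 1 fell, 31 and 1 adjusted over the list alone (adjusted p = 1.81e-04, and 0.0831 with an estimated correlation). The adipocyte (adjusted p = 1.14e-05, and 0.0266 with an estimated correlation), sebaceous (adjusted p = 1.90e-05, and 0.0266 with an estimated correlation), Schwann cell (adjusted p = 9.10e-05, and 0.0775 with an estimated correlation), melanocyte (adjusted p = 9.10e-05, and 0.0709 with an estimated correlation) and Wnt lists (adjusted p = 9.10e-05, and 0.0831 with an estimated correlation) rose, with Adipoq at 4.46 ± 0.266. In the neutrophil list 0 of 15 rose and 15 fell (adjusted p = 5.89e-06, and 0.0102 with an estimated correlation), and S100a8 fell by 6.10 ± 0.418 (adjusted p = 5.44e-07). The cytokine (adjusted p = 7.23e-04, and 0.093 with an estimated correlation), cell cycle (adjusted p = 0.00894, and 0.333 with an estimated correlation) and wound-edge lists (0 of 25 rose and 21 fell, adjusted p = 2.46e-07, and 7.79e-04 with an estimated correlation) fell, with Il6 at -4.13 ± 0.328, Plk1 at -1.47 ± 0.223 and Krt6a at -5.89 ± 0.215, adjusted p = 2.64e-12. Tnc fell by 2.34 ± 0.203 and Pecam1 by 0.55 ± 0.138 (adjusted p = 0.0581 with DESeq2), and Mki67 fell by 0.43 ± 0.153 (adjusted p = 0.0427), a call lost without Acomys day 7 replicate 1, 2 or 4 or Acomys day 14 replicate 1 or 4, adjusted p = 0.0628 to 0.148. Col3a1 rose by 0.70 ± 0.24, adjusted p = 0.0386, a call lost without Acomys day 7 replicate 1, 2 or 4 or Acomys day 14 replicate 1, 2, 3 or 4, adjusted p = 0.0528 to 0.133. Col1a1 (0.58 ± 0.293, adjusted p = 0.169) and Emr1 (-0.59 ± 0.44, adjusted p = 0.377) did not pass, but Col1a1 did with only the groups compared (adjusted p = 0.021). Postn (0.52 ± 0.238, adjusted p = 0.124) passed without Acomys day 7 replicate 3, adjusted p = 0.00507.

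**Figure D2:**
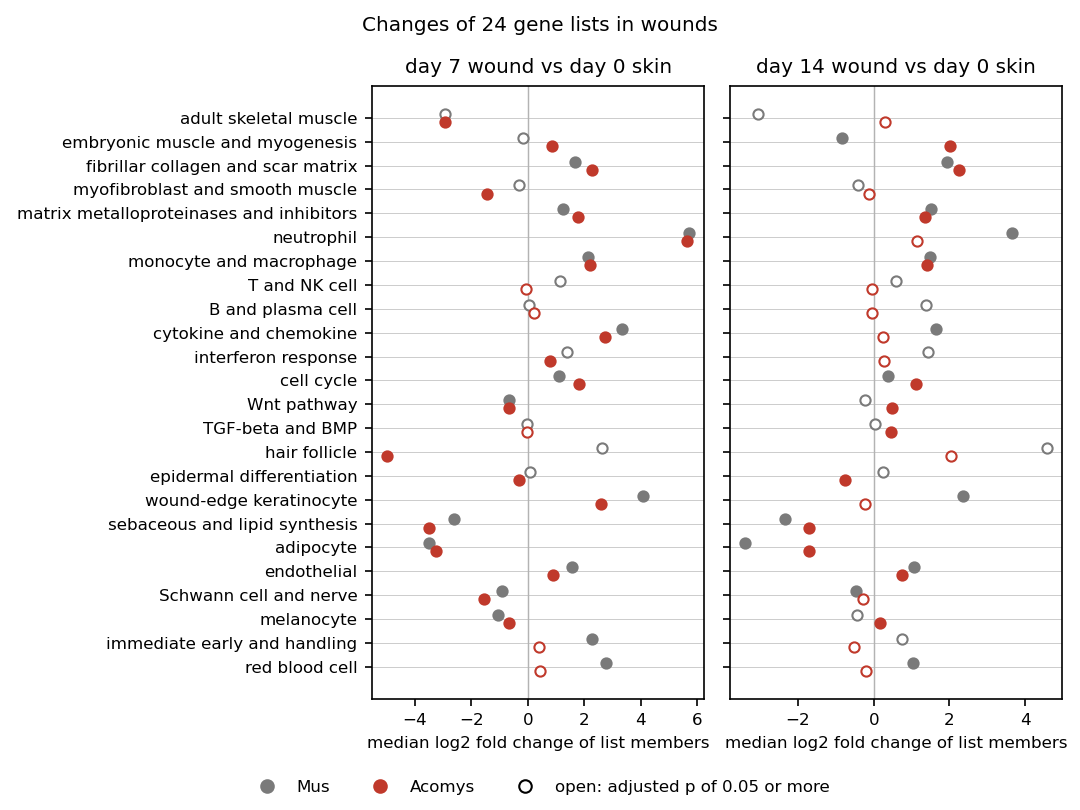
Median log2 fold change of the measured members of each of the 24 lists, wound against day 0 skin at day 7 (left) and day 14 (right), in Mus (grey) and Acomys (red), with open points where the list's adjusted p was 0.05 or more. The hair follicle list lies at 2.63 in Mus and -4.99 in Acomys at day 7, and the embryonic muscle list at -0.83 and 2.02 at day 14.

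The difference of the day 7 changes between the species asks which wound responses differ early in healing, in the shared table. On balance the hair follicle, sebaceous, fat, endothelial, neutrophil and cytokine lists moved lower in Acomys than in Mus by fry, but with an estimated correlation none was called (adjusted p = 0.817 each), and the hair follicle, neutrophil and cytokine calls were lost in several fits without 1 library. Most genes called in both species moved the same way.

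At day 7, 5193 of 14514 genes differed in their change, 2486 with a higher and 2707 with a lower change in Acomys. The embryonic muscle list was not called (adjusted p = 0.0958), though Tnnt2 and Chrna1 had a higher change by 2.15 ± 0.483 and 1.64 ± 0.436. Myh3 was at 4.77 ± 0.875, adjusted p = 3.32e-04 in the shared table, but rose by 4.19 in Mus and 4.87 in Acomys in their own tables. Mus day 0 Myh3 was at 0.465 ± 0.106 CPM in the mouse-only table and 6.75 ± 0.676 CPM in the shared one, so its value depends on the table. In the hair follicle list 1 of 32 were higher and 21 lower, 1 and 25 adjusted over the list alone (adjusted p = 0.0284), but 6 of 15 fits without 1 library lost the call, adjusted p 0.0166 to 0.07. The inner-root-sheath keratins Krt71 and Krt27 were at -13.63 ± 2.46 and -13.92 ± 2.91 and the companion-layer keratin Krt75 at 2.57 ± 0.403. In the adipocyte list 1 of 21 were higher and 12 lower, 1 and 13 adjusted over the list alone (adjusted p = 0.0142). Adipoq was at -3.74 ± 0.956, adjusted p = 0.00506 and Pparg at -1.44 ± 0.248. In the sebaceous list 2 of 20 were higher and 11 lower, 2 and 13 adjusted over the list alone (adjusted p = 0.00502). In the endothelial list 2 of 22 were higher and 11 lower, 2 and 12 adjusted over the list alone (adjusted p = 0.012). Pecam1 was at -1.16 ± 0.157, adjusted p = 7.72e-06. The neutrophil list was lower (adjusted p = 0.0473), but 10 of 15 fits without 1 library lost the call, adjusted p 0.0282 to 0.118. The cytokine list was lower too (adjusted p = 0.0284), but 7 of 15 fits without 1 library lost the call, adjusted p 0.00571 to 0.07. The matrix metalloproteinase list was called higher (9 of 24 were higher and 7 lower, 10 and 8 adjusted over the list alone, although its median was -0.22, mean 0.13, adjusted p = 0.0473), but 12 of 15 fits without 1 library lost the call, adjusted p 0.00595 to 0.107.

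The day 7 change of Col12a1 was lower in Acomys (-2.04 ± 0.345) and that of Lox was higher (2.42 ± 0.257). Col1a1 (1.15 ± 0.472, adjusted p = 0.0622), Col3a1 (0.58 ± 0.339, adjusted p = 0.191), Tnc (0.93 ± 0.393, adjusted p = 0.0708) and Acta2 (-0.74 ± 0.306, adjusted p = 0.0643) did not pass. With all libraries, Col1a1 did with DESeq2, only the groups compared or the block (adjusted p = 0.0376, 0.0441 and 0.0301), Tnc with DESeq2 or only the groups compared (0.0486 and 0.0247) and Acta2 with the block (0.0353). Leaving out 1 library also made the call for Col1a1 (without Acomys day 0 replicate 1, adjusted p = 0.0131), Col3a1 (without Acomys day 0 replicate 1, adjusted p = 0.0205), Tnc (without Mus day 0 replicate 1, adjusted p = 0.0461) and Acta2 (without Acomys day 7 replicate 3 or Mus day 7 replicate 3 or 4, adjusted p = 0.0276 to 0.0456). Myog was at 1.64 ± 0.751, adjusted p = 0.0946, and passed without Acomys day 0 replicate 4, adjusted p = 0.0479. Myod1, Myh8, Ckm, Acta1, Postn, Mki67, S100a8, Emr1 and Krt6a did not pass in their change (adjusted p = 0.799, 0.953, 0.593, 0.237, 0.729, 0.352, 0.157, 0.104 and 0.997). Acta1 did without the 3 muscle-poor libraries (adjusted p = 0.0016), and Myh8 depends on the table, being called lower at day 7 in the Acomys table and not called in the Mus table.

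The difference of the day 14 changes asks where the species part later. On balance the embryonic and adult muscle, Wnt and melanocyte lists moved higher in Acomys by fry, and the wound-edge, endothelial and neutrophil lists lower. With an estimated correlation none was called, and the adult muscle, Wnt, endothelial and neutrophil calls were lost in some fits without 1 library.

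At day 14, 3649 genes differed in their change, 1905 with a higher and 1744 with a lower change in Acomys. In the embryonic muscle and myogenesis list 17 of 23 were higher and 0 lower, 18 and 1 adjusted over the list alone (adjusted p = 6.86e-05, and 0.169 with an estimated correlation). Myh3 had a higher change by 7.33 ± 0.948, adjusted p = 2.03e-05, Myog by 5.98 ± 0.934, adjusted p = 9.42e-05, Tnnt2 by 4.22 ± 0.489, Chrna1 by 3.55 ± 0.439 and the thick-filament gene Mybph by 6.13 ± 0.763. Myod1 (adjusted p = 7.37e-04) differed too, with 0.0416 ± 0.0832 CPM in Mus and 4.63 ± 1.28 CPM in Acomys in the shared table. Myh8 was higher by 5.29 ± 1.57, adjusted p = 0.0185, a call lost without Acomys day 14 replicate 2, adjusted p = 0.0552. In their own tables Mus and Acomys Myh3 changed by 0.51 and 5.77 and Myh8 by -3.10 and 0.42, smaller differences, so the size of both depends on the table. In the adult skeletal muscle list 12 of 39 were higher and 1 lower, 19 and 2 adjusted over the list alone (adjusted p = 0.0418, and 0.642 with an estimated correlation), and 11 of 15 fits without 1 library lost the call, adjusted p 0.00474 to 0.0764. Ckm (3.01 ± 1.76, adjusted p = 0.229) and Acta1 (3.84 ± 1.58, adjusted p = 0.0846) passed without Mus day 14 replicate 1 (adjusted p = 0.0333 and 0.0142), and Acta1 also with DESeq2 (adjusted p = 0.0413), the block or the 3 muscle-poor libraries left out (adjusted p = 0.0396 and 5.50e-04). In the wound-edge keratinocyte list 0 of 25 were higher and 13 lower, 0 and 14 adjusted over the list alone (adjusted p = 6.86e-05, and 0.169 with an estimated correlation). Krt6a was at -4.97 ± 0.447, adjusted p = 1.66e-07 and Krt16 at -7.13 ± 0.684. In the Wnt list 17 of 49 were higher and 7 lower, 18 and 7 adjusted over the list alone (adjusted p = 0.02, and 0.642 with an estimated correlation), but 1 of 15 fits without 1 library lost the call, adjusted p 0.00714 to 0.0502. In the melanocyte list 3 of 9 were higher and 0 lower (adjusted p = 0.0016, and 0.544 with an estimated correlation).

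The day 14 change of S100a8 was lower in Acomys (-4.08 ± 0.768, adjusted p = 7.13e-04), within a neutrophil list called lower (0 of 15 were higher and 5 lower, adjusted p = 0.032, and 0.642 with an estimated correlation), but 5 of 15 fits without 1 library lost the call, adjusted p 0.0171 to 0.0764. Pecam1 was lower (-1.12 ± 0.158, adjusted p = 2.76e-05), within an endothelial list called lower (1 of 22 were higher and 7 lower, 1 and 9 adjusted over the list alone, adjusted p = 0.032, and 0.642 with an estimated correlation), but 5 of 15 fits without 1 library lost the call, adjusted p 0.0178 to 0.0654. Acta2 was lower (-0.96 ± 0.307, adjusted p = 0.026), a call lost without Acomys day 0 replicate 2 or Acomys day 14 replicate 2 or Mus day 0 replicate 1 or 4 or Mus day 14 replicate 4, adjusted p = 0.0521 to 0.0613. Col1a1 (1.12 ± 0.472, adjusted p = 0.0878), Col3a1 (0.61 ± 0.339, adjusted p = 0.196) and Mki67 (0.44 ± 0.208, adjusted p = 0.128) did not pass, but did, in this order, without Acomys day 0 replicate 1 or Mus day 14 replicate 2, adjusted p = 0.0209 to 0.0215, without Acomys day 0 replicate 1, adjusted p = 0.0237, and without Acomys day 14 replicate 4 or Mus day 0 replicate 1, adjusted p = 0.0443 to 0.0455. Col1a1 also passed with the block or without the 3 muscle-poor libraries (adjusted p = 0.0428 and 0.0188). Tnc, Postn, Emr1 and Adipoq did not pass in their change (adjusted p = 0.756, 0.34, 0.61 and 0.203).

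**Figure D3:**
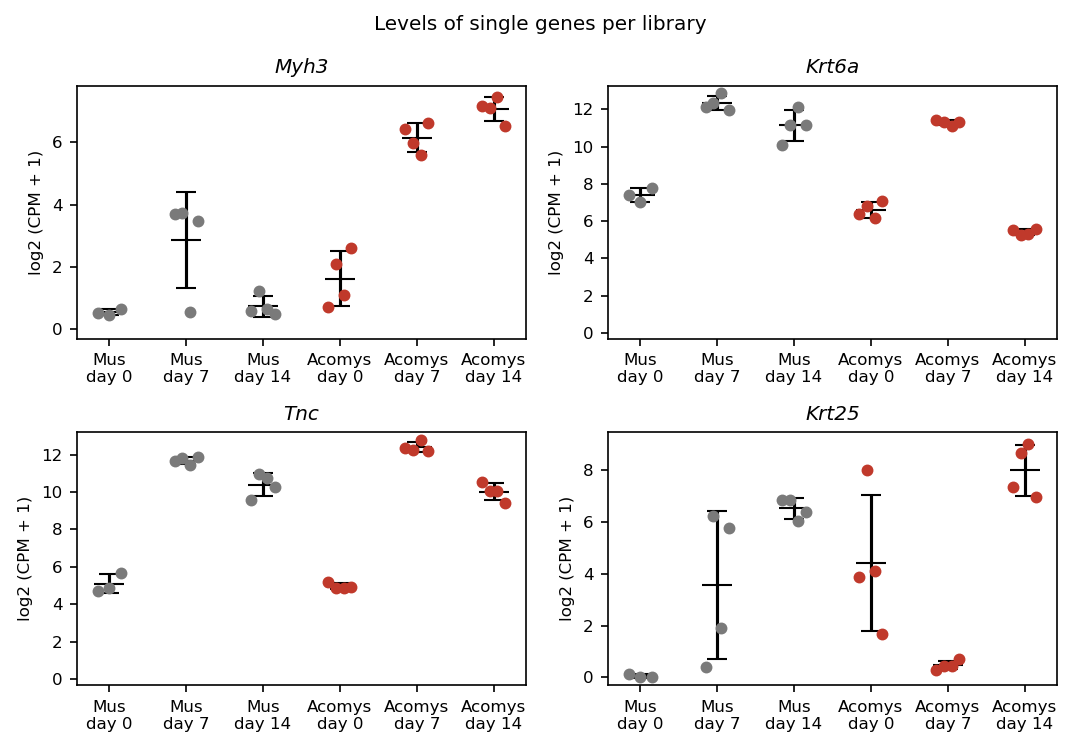
Level of Myh3, Krt6a, Tnc and Krt25 as log2 of CPM + 1 in each library (points), with the mean and SD of each group (bars), in the count table of each species. Myh3 is at 0.693 ± 0.432 CPM in Mus and 137 ± 34.4 CPM in Acomys at day 14, and Krt6a at 2564 ± 1440 and 42.2 ± 4.66 CPM.

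Direct comparisons of the species at one day are secondary to the differences of changes, as gene length and reference differ. In the shared table Srsf3 and others had no Mus count, which can add to genes called, in changes too. In unwounded skin, 9530 genes differed, 5002 higher and 4528 lower in Acomys, with fibrillar collagen and macrophage transcripts lower. Col1a1 (-1.56 ± 0.346), Col3a1 (-2.28 ± 0.252), Emr1 (-3.36 ± 0.372) and Myh8 (-8.30 ± 0.91) were lower, while Acta2 (0.96 ± 0.229), Postn (0.72 ± 0.237), S100a8 (2.20 ± 0.637) and Pecam1 (1.12 ± 0.118) were higher. Mus day 0 Myh8 was at 7.76 ± 1.25 CPM in the mouse-only table and 165 ± 24.7 CPM in the shared table, so its value depends on the table. Krt6a was at -0.88 ± 0.302, adjusted p = 0.0142, a call lost without Mus day 0 replicate 4, adjusted p = 0.0737. The collagen (6 of 30 were higher and 18 lower, 6 and 19 adjusted over the list alone, adjusted p = 4.51e-06), macrophage (adjusted p = 0.00229) and B and plasma cell lists (adjusted p = 4.51e-06) were called, the last upward, but had 0.978 with an estimated correlation. Myh3, Myod1, Myog, Ckm, Acta1, Tnc, Mki67 and Adipoq did not pass (adjusted p = 0.208, 0.649, 0.427, 0.421, 0.203, 0.416, 0.392 and 0.153). With only the groups compared Ckm, Acta1 and Adipoq did (adjusted p = 0.0038, 1.78e-04 and 4.68e-04).

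At day 7, 10286 genes differed between the wounds, 5217 higher and 5069 lower in Acomys. Myh3 was higher by 3.77 ± 0.556, adjusted p = 6.70e-06, and the embryonic muscle list was higher (13 of 23 were higher and 2 lower, 12 and 2 adjusted over the list alone, adjusted p = 0.00444). Krt6a (-0.87 ± 0.282), Krt16 (-8.12 ± 0.473) and Krt17 (-9.32 ± 0.434) were lower, in a wound-edge list that was lower (adjusted p = 0.00444). Both lists had 0.983 with an estimated correlation. Col3a1 (-1.70 ± 0.237), Emr1 (-2.33 ± 0.329) and Adipoq (-2.85 ± 0.781) were lower. Myh8 was at 11.7 ± 8.53 CPM in Mus and 0.0247 ± 0.0493 CPM in Acomys (adjusted p = 4.64e-05). Myog (1.11 ± 0.489, adjusted p = 0.0477), Tnc (0.65 ± 0.264, adjusted p = 0.0331) and Postn (0.55 ± 0.216, adjusted p = 0.0274) were higher, calls lost for Myog without Acomys day 7 replicate 1, 2 or 4 or Mus day 7 replicate 3 or 4, adjusted p = 0.0601 to 0.145, for Tnc without Acomys day 7 replicate 1 or 3 or Mus day 7 replicate 1 or 3, adjusted p = 0.0608 to 0.0957, and for Postn without Acomys day 7 replicate 3 or Mus day 7 replicate 1, 3 or 4, adjusted p = 0.0567 to 0.221. Acta2 (0.22 ± 0.206, adjusted p = 0.344) passed without Mus day 7 replicate 2, adjusted p = 0.0236. Ckm (-2.55 ± 1.27, adjusted p = 0.0809) passed without Mus day 7 replicate 3, adjusted p = 0.034, and with DESeq2, only the groups compared or the 3 muscle-poor libraries left out (adjusted p = 0.0455, 0.0483 and 5.67e-05). Acta1, Myod1, Col1a1, Mki67, S100a8 and Pecam1 did not pass (adjusted p = 0.532, 0.356, 0.261, 0.507, 0.0961 and 0.759), but S100a8 did with only the groups compared (adjusted p = 0.0289).

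At day 14, 10553 genes differed, 5533 higher and 5020 lower in Acomys. Myh3 was higher by 6.33 ± 0.657, adjusted p = 7.35e-08 and Myog by 5.45 ± 0.685, and the embryonic (19 of 23 were higher and 2 lower, adjusted p = 1.50e-07) and adult muscle lists (22 of 39 were higher and 1 lower, 21 and 1 adjusted over the list alone, adjusted p = 0.00189) were higher. Myod1 had adjusted p = 1.99e-06. The wound-edge list was lower (0 of 25 were higher and 23 lower, adjusted p = 1.50e-07). Krt6a was at -5.86 ± 0.346, adjusted p = 5.39e-12. The hair follicle list was higher (adjusted p = 0.0151), but 1 of 8 fits without 1 library lost the call, adjusted p 0.0097 to 0.0529. The adipocyte list was higher (15 of 21 were higher and 2 lower, adjusted p = 2.41e-05). With an estimated correlation each of these 5 lists had 0.877. Adipoq was at 2.32 ± 0.593. S100a8 (-1.88 ± 0.435), Emr1 (-2.98 ± 0.34) and Col3a1 (-1.67 ± 0.237) were lower. Myh8 was lower (-3.02 ± 0.912, adjusted p = 0.00627), a call lost without Mus day 14 replicate 1, adjusted p = 0.0601, but was at 0.906 ± 0.762 CPM in Mus and 0.957 ± 0.524 CPM in Acomys in their own tables, so this depends on the table. Ckm (1.81 ± 1.22, adjusted p = 0.19) and Acta1 (2.15 ± 1.10, adjusted p = 0.0863) passed without Mus day 14 replicate 1 (adjusted p = 0.0134 and 0.00858), and Acta1 also with DESeq2 or without the 3 muscle-poor libraries (adjusted p = 0.0458 and 0.0104). Tnc (-0.48 ± 0.264, adjusted p = 0.108) passed without Acomys day 14 replicate 1 or Mus day 14 replicate 1, adjusted p = 0.0162 to 0.0183. Mki67 (0.29 ± 0.141, adjusted p = 0.0703) passed without Acomys day 14 replicate 4, adjusted p = 0.0141, and with only the groups compared (adjusted p = 0.0488). Col1a1, Acta2, Postn and Pecam1 did not pass (adjusted p = 0.224, 0.999, 0.245 and 0.998).

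The wound responses of Mus and Acomys were also compared over all 14514 shared genes, which are not independent replicates. At day 7 the log2 fold changes had a Pearson correlation of 0.528 across genes (jackknife SE over libraries 0.0478) and a Spearman correlation of 0.543. Of 5603 genes called in both species, 4914 (87.7%) moved the same way: 2423 rose in both, against 1188.4 if the species were independent, and 2491 fell in both, against 1217.7. At day 14 the Pearson correlation was 0.444 (jackknife SE 0.0555) and the Spearman correlation 0.429, and 2859 of 3250 genes called in both (88.0%) moved the same way, 1440 upward and 1419 downward. Tnc, Postn, Emr1, Trem2 and Mki67 are among the genes that rose in both species at day 14, and Adipoq among those that fell.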

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

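The test that leaves out single libraries for the hair follicle result was planned; every other test in this part was chosen only after the result was seen.

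Muscle transcripts set the species apart at day 14: the change of the embryonic muscle and myogenesis list was higher in Acomys than in Mus (adjusted p = 6.86e-05, and 0.169 with an estimated correlation), as was that of the adult skeletal muscle list (adjusted p = 0.0418, and 0.642 with an estimated correlation; lost in 11 of 15 fits without 1 library). Uninjured adult muscle in the Acomys samples would raise both lists alike, but by fitted medians the embryonic list stood 1.72 log2 higher. Levels per library (embryonic 1.402 to 1.927, adult -0.387 to 0.933) also argue against it as the embryonic source. Adjacent skin would bring fat and sebaceous transcripts, but the adult list stood 2.01 log2 above the higher of those. This argues against skin at day 0 levels. Muscle alone at the sample margin cannot be told from new adult fibres: its level varied by an SD of 0.547 log2 between the Acomys libraries and 2.95 log2 between the Mus libraries, and an even share of muscle would also give a small spread. New muscle forming in the Acomys wound is a hypothesis for the embryonic list standing above skin. Histology of the wound bed would decide it.

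The hair follicle list moved lower in Acomys than in Mus at day 7 (adjusted p = 0.0284, and 0.817 with an estimated correlation), with 21 members called lower. The call was lost without Acomys day 7 replicate 2, Mus day 0 replicate 1, 2 or 4, or Mus day 7 replicate 2 or 4 (adjusted p = 0.0557 to 0.07), and the Mus medians at day 7 were -0.18, 2.416, 0.194 and 1.939 in replicates 1 to 4. Acomys day 0 replicate 2 had a median of 1.371, against -0.388 to -0.376 in the other 3 Acomys skin libraries, and without it 13 members were called lower, so part of the result leans on that library. A larger share of epithelium in the Mus samples, acting alone, would raise follicle genes together, but 10 members fell in Mus while 17 rose. Regulation of single genes can act on top of tissue share, and the count covers Mus only, so this cannot exclude it. Over 15 fits without 1 library, 13 to 23 members were called lower. One hypothesis is that follicles at the Mus wound edge had entered growth while those of Acomys had not, though 10 members fell in Mus and 1 Acomys skin library stood apart; staging of follicles in sections would test it.

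The number of genes whose change differed between the species (5193 at day 7, 3649 at day 14) was itself picked out. Each of the 11 comparisons was set against other splits of its libraries. These fits hold only the groups compared, so counts differ from those above. In the 9 contrasts of 2 groups, only the real one of all 35 splits gave as many genes. The real counts and the highest of the other splits were, for Mus, 9092 against 1 (day 7 with day 0), 6823 against 107 (day 14 with day 0) and 2789 against 43 (day 14 with day 7). For Acomys they were 13784, 7020 and 8855 against 0 each time, and between the species 9348, 9749 and 10136 against 0 (days 0, 7 and 14). For the differences of changes, 1 of 100 splits, the real one, gave as many, with 4969 against 2242 at day 7 and 3547 against 911 at day 14. These do not test equal changes. In the other 9 chance is unlikely if libraries are independent.

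Other lists whose day 7 change differed between the species by fry were the following, the first higher in Acomys and the rest lower: matrix metalloproteinases and inhibitors (adjusted p = 0.0473), neutrophil (0.0473), cytokine and chemokine (0.0284), sebaceous and lipid synthesis (0.00502), adipocyte (0.0142), endothelial (0.012), Schwann cell and nerve (0.0284), immediate early and handling (0.0284) and red blood cell genes (0.0142). Of 15 fits without 1 library, 12, 10, 7, 0, 0, 0, 4, 4 and 1 lost these calls. Among single genes, the day 7 changes of Myh3 (0.000332, though in the species' own tables it rose in both), Adipoq (0.00506) and Pecam1 (7.72e-06) differed. At day 14 the lists of neutrophil (0.032), epidermal differentiation (0.0418), wound-edge keratinocyte (6.86e-05) and endothelial genes (0.032) were lower and those of Wnt pathway (0.02), TGF-beta and BMP (0.0437), sebaceous and lipid synthesis (0.0494) and melanocyte genes (0.0016) higher, and 5, 10, 0, 5, 1, 11, 12 and 0 of 15 fits lost these calls. With an estimated correlation camera called 0 lists at either day. Genes whose day 14 change differed were Myh3 (2.03e-05) and Myh8 (0.0185), both of a size that depends on the table, Myod1 (0.000737), Myog (9.42e-05), Acta2 (0.026), S100a8 (0.000713), Krt6a (1.66e-07) and Pecam1 (2.76e-05).

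Of 98 groups of 4 values examined for a library far from the others, 8 had one, and about 4.9 (1 in 20) would by chance. Mus day 14 replicate 2 had 10.85% small structural RNA (95% Wilson interval 10.83 to 10.87%), below the other 3 libraries. Mus day 14 replicate 1 had 0.0969 CPM of Myod1 against 0, and 0.678 CPM of Myog against 0 to 0.111. Mus day 7 replicate 3 had 0.158 CPM of Myh8 against 23.0 to 26.6. Acomys day 0 replicate 1 had 35.6 CPM of Tnc against 28.4 to 29.5. In Acomys at day 7, replicate 1 had 0.0574 CPM of Myh8 against 0, replicate 2 had 359 CPM of Acta1 against 409 to 415, and replicate 3 had 0.24 CPM of Pax7 against 1.24 to 1.35.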

How the results depend on the processing

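The settings that leave out small structural RNAs or the 3 muscle-poor mouse libraries, and single libraries left out for the lists, were chosen only after the results were seen; the other settings were planned. No called list reversed its direction under any setting. With RLE size factors, DESeq2, only the groups compared, the replicate block, small structural RNAs left out, the muscle-poor libraries left out or 1 library left out, each number of genes past FDR 0.05 stayed within 1.5 times that with all data, and the share that was higher moved by at most 5.67 points. A minimum of 2-fold, which by construction keeps fewer genes, left 4297 (Mus day 7 against day 0), 3173 (Mus day 14 against day 0), 1215 (Mus day 14 against day 7), 4906 (Acomys day 14 against day 0), 5929 (Acomys day 14 against day 7), 4601, 5076 and 5182 (Acomys against Mus at days 0, 7 and 14), and 2658 and 1924 genes (differences of changes at days 7 and 14). Acomys day 7 against day 0 gave 25653 features with no filter on low counts, which tests more features, and 9220 with counts summed by symbol, which tests fewer. The list calls depended most on the test: camera differs from fry in its correlation and in comparing a list with other genes. Fry called 15, 13 and 12 lists in the Mus contrasts (day 7 and day 14 against day 0, day 14 against day 7), 19, 12 and 17 in the Acomys ones, 11, 14 and 18 between the species at days 0, 7 and 14, and 10 and 10 in the differences of changes. Camera with an estimated correlation called 0, 1, 0, then 6, 5, 4, then 0, 0, 0, and 0 and 0; the cause was not tested. With a preset correlation camera called 1, 0 and 6 lists between the species at days 0, 7 and 14 and 6 in the difference at day 7; the cause was not tested. For the difference at day 14, the adult skeletal muscle list went from adjusted p = 0.0418 to 0.642 and the embryonic list from 6.86e-05 to 0.169 with an estimated correlation; the cause was not tested. Between the species at day 7, 9 lists were called without Acomys day 7 replicate 1. Leaving out 1 library gave 0.0047 to 0.0764 for that adult list. Of 151 list calls in 264 tests, 107 held in every fit without 1 library and 44 were lost in at least 1. Of the 151, 4 were lost with RLE, 4 with the block (15 were gained), 5 without small structural RNAs (1 gained) and, in the 168 tests with mouse wounds, 10 without the muscle-poor libraries (13 gained). The block changed no other call in Mus day 7 or day 14 against day 0 than those given in the results. Between Mus day 7 and day 14, 3 of 4 same-number pairs correlated above 0.1 (range 0 to 0.598). Replicate 2 was not closest to its own number. There the block gave 4406 genes against 3685. Over genes with a mean CPM of at least 10, the correlation of the species' fold changes was higher, with Pearson 0.638 and Spearman 0.613 at day 7 and 0.545 and 0.497 at day 14; the cause was not tested. Depth limits what can be said of Myod1 and Myog in Mus, which were at a few counts or none in some libraries, and in the shared table genes were kept only from 110 counts in total.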

Other observations

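Most genes of the circadian clock that peak with Dbp were lower in wounds than in skin of both species. This set was chosen only after Dbp had appeared among the genes that fell most, and both tests of it were chosen only after the result was seen. Of 11 genes that peak with Dbp, a clock output factor, 9 fell in Mus at day 7, 10 in Mus at day 14, 10 in Acomys at day 7 and 11 in Acomys at day 14, with median log2 changes of -2.12, -1.997, -2.52 and -2.19. The same 9 fell in all 4 comparisons. In Mus at day 7 Dbp fell by 3.85 ± 0.216, its relatives Hlf and Tef by 3.55 ± 0.218 and 2.47 ± 0.11, the repressor Nr1d1 by 2.12 ± 0.125 and Per3 by 2.48 ± 0.174. Per1 moved the other way there, with a rise of 0.97 ± 0.341 (adjusted p = 0.0313).

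The 4 genes that peak with Arntl, in the opposite phase, had medians of 0.935 and 1.34 in Mus and 1.12 and 0.647 in Acomys at days 7 and 14. Npas2, a partner of the clock activator, rose in 4 of 4 comparisons and Arntl in 3 of 4. The Arntl phase had a median of 0.948 over the 4 comparisons. As the hour is unknown, this cannot exclude fewer cells with a running clock. Tissue taken at another hour would lower the Dbp phase, whose median was -2.10, and raise the other; a change of the clock within wounds would do the same, and the labels give no hour, so these cannot be told apart. Wounds and skin taken at one hour would test the hour.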
